A study of Mus musculus with 2 samples.

How the data were processed

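RNA was measured in macrophages of the mouse peritoneal cavity with 1 Affymetrix 3' expression array per group. The resident array held RNA from macrophages of untreated C57BL/6J mice. The elicited array held RNA from macrophages collected 3 days after an intraperitoneal injection of 1 mL of 3% thioglycollate, a broth that draws leukocytes into the cavity as a sterile irritant. Per the labels' protocols, mice were 8 weeks old, cells adhered for 2 h before non-adherent cells were washed off, and biotinylated cRNA was made from 100 ng of total RNA. The series description instead speaks of overnight culture, so the time in culture is uncertain. How many mice were pooled for each array is not given in the sources used here.

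The deposited values are linear signal intensities, 1 per probe set, for 45101 probe sets per array. They were made by the authors with MAS5, per the submitters' processing notes. Its version, its detection calls and its scaling target are not given in the sources used here. The mean of the deposited intensities after leaving out the lowest and highest 2% of probe sets was 499.8 on both arrays, so the table is scaled to a common trimmed mean. No other normalization was applied for the main results. Values were compared on the log2 scale as elicited minus resident.

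Genes were named from the platform annotation, with symbols updated by gene ID to the GRCm38.p6 RefSeq gene table (34754 of 34958 probe sets with 1 symbol matched; the other 204 kept their older symbol). A further 932 probe sets listed several genes and 9211 had no gene listed here, 9160 of them not array controls. These stayed out of the gene-level results, as did array controls. The array's own coordinates are not used here, so no genome positions are given.

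Detection calls were not used here, so a floor was set from gene families that macrophages are not thought to express (olfactory, vomeronasal and bitter taste receptors and keratin-associated proteins). The floor was a signal of 82.2, the 95th percentile of the 252 values of their 126 probe sets over both arrays. Lower signals were raised to the floor, so a ratio against an array at or below it is a bound and is written as at least N-fold. Each gene was represented by its probe set with the highest mean log2 signal. Of 18193 named genes, 11499 were above the floor on at least 1 array and 9820 on both.

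With 1 array per group there is no replicate, and no test between the conditions was run. Differences are described against a 2-fold threshold. The only spread that could be measured was that between probe sets of the same gene. Its SD was 0.48 on the log2 scale (1.40-fold), over 4465 genes with at least 2 probe sets above the floor on both arrays. It covers probe and hybridisation differences within these arrays, not differences between animals or cultures. The number of arrays limits the precision of all values.

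There were 36 gene lists fixed before the data were examined (1 of key macrophage genes, 23 of pathways, 10 of cell type markers and 2 of controls). Of their 555 genes, 52 had no probe set naming that gene alone and were not analysed here. For each list with at least 3 members above the floor, the median log2 ratio was placed among 10000 random lists of the same size matched on mean signal in 20 bins. This percentile describes these 2 arrays and is not a test of the conditions. List medians hold floored genes at their bound.

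Genes named in the text were chosen by a rule fixed at the same time. The rule took the 12 highest and 12 lowest ratios among genes above the floor on both arrays whose probe sets agreed in direction, and the 8 brightest genes in each direction that were at or below the floor on the other array. It also took the key macrophage genes and up to 4 members with the largest absolute log2 ratio in each list. Genes with only a clone identifier were skipped in the first 2 steps. Further list members are named to account for a small count or describe a group, and these were chosen after their values were seen.

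The calculations were tested on simulated data: an array pair drawn from the real probe-set means, with noise equal to the probe-set SD and 200 changed genes. At 4-fold, 50 of 50 raised genes and 45 of 50 lowered genes passed the 2-fold threshold. At 8-fold, 50 of 50 did in each direction. Of 10785 unchanged genes, 393 (3.64%) passed it. Of 100 unchanged lists of 20 genes, 3 lay outside the central 95% of random lists.

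Alternatives changed the scaling, the floor, the choice of probe sets and the filter on dim genes. The scalings were equal medians of the probe sets above the floor on both arrays, quantile, and loess with a span of 0.4. For the floor they were the 99th percentile (a signal of 174), a pseudocount of 1 and the floor added as a pseudocount. Scaling on the spiked hybridisation controls, and a floor from the resident array alone (92.7), were added after the data were seen. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.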

Results

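Expression profiles were compared between mouse peritoneal macrophages that reside in the untreated cavity and those recruited by thioglycollate, both after adherence in culture. Each group was represented by 1 array, so no value below carries a replicate error and no difference was tested against variation between animals or cultures. Signals exceeded the floor of 82.2 at 51.9% of probe sets on the resident array and at 46.1% on the elicited array. The silent families alone had a 95th percentile of 92.7 on the resident and 67.9 on the elicited array. The shared floor thus let more background pass on the resident array, and part of the gap in these shares can come from it. The median signals were 91.5 and 67.8. Over the 19301 probe sets above the floor on both arrays, log2 signals correlated across probe sets with Pearson's r = 0.891 and Spearman's rho = 0.872; probe sets are not independent replicates. Signs of RNA quality were alike on both arrays. The 3' to 5' signal ratio was 1.19 on the resident and 1.22 on the elicited array for beta-actin, and 0.587 and 0.5999 for Gapdh.

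Transcripts that mark resident peritoneal macrophages, such as Alox15, Timd4 and Cxcl13, were far lower on the elicited array, and lysosomal and matrix genes such as Ctsk, Gpnmb and Sparc were higher. Of 11499 genes above the floor, 924 were at least 2-fold higher and 1357 at least 2-fold lower on the elicited array. At 4-fold the counts were 203 and 316. The remaining 9218 genes (80.2%) had ratios under 2-fold, but 1229 of these are bounds against the floor, so their true ratios can be larger. The same holds for list members counted as within 2-fold whose signal was at or below the floor on 1 array. Of the 1150 genes at least 2-fold apart that had 2 or more probe sets above the floor, 1028 (89.4%) had every probe set in the same direction. In a simulated array pair with noise equal to the probe-set spread, 3.64% of unchanged genes passed the 2-fold threshold. That share follows from the noise level chosen. The simulation held no differences between animals or cultures and no trend with signal, so the share is not a false-call rate for these arrays.

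The balance between higher and lower genes depended on the scaling. Of all genes at least 2-fold apart, 40.5% were higher on the elicited array as deposited. The share was 65.9% after scaling to equal medians of the probe sets above the floor on both arrays. It was 57.9% after quantile normalization, 50.2% after removing a loess trend and 18.2% after scaling on the spiked hybridisation controls. These controls, added in fixed amounts, were 1.29-fold higher on the elicited array in the deposited values, in 9 of 9 probe sets. The array's poly-A controls were 1.31-fold higher, in 12 of 12 probe sets, and its 18S rRNA controls 1.24-fold higher, in 3 of 3. The median log2 ratio of all genes was -0.03 as deposited, 0.25 with equal medians, 0.16 with quantile normalization, 0.07 with loess and -0.36 on the hybridisation controls. The ratio also varied with signal: among genes above the floor on both arrays its median was -0.24 in the third decile of mean signal and 0.41 in the brightest. Differences below are on the deposited scale, and each list is therefore set against random lists of the same signal.

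**Figure D1:**
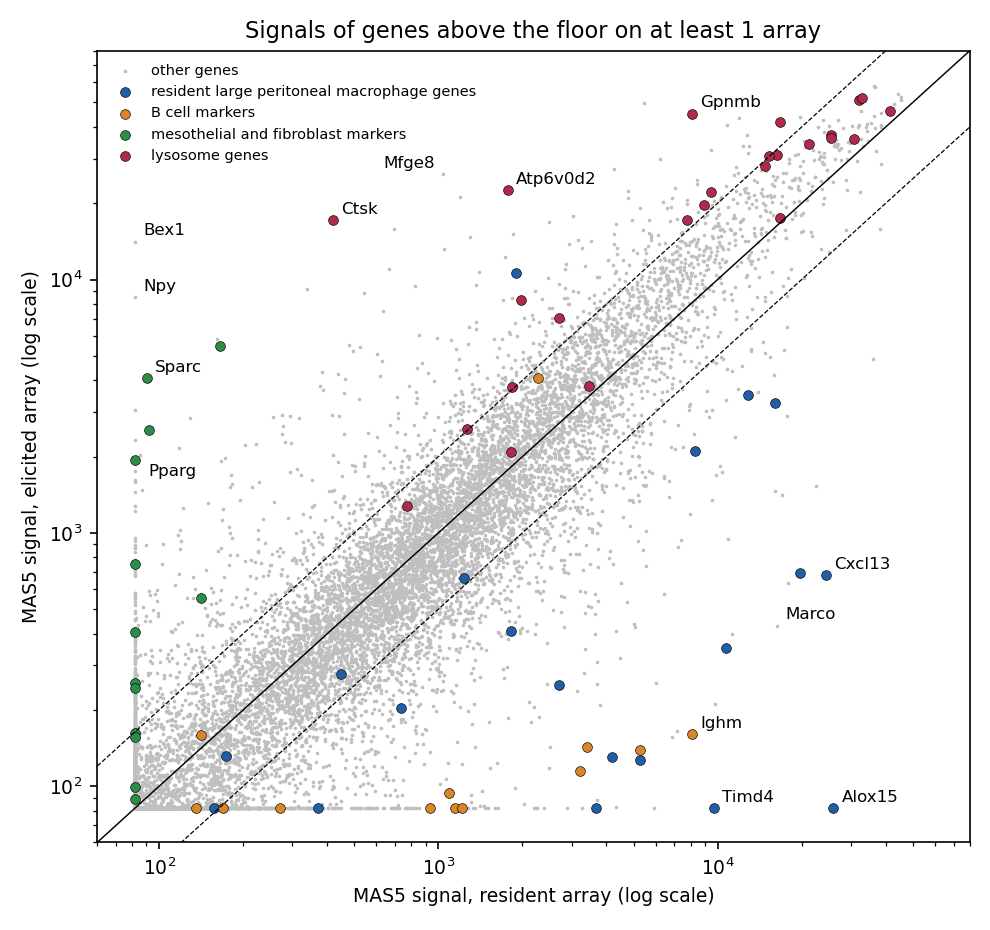
MAS5 signal of each gene on the resident array (x axis) and the elicited array (y axis), both on log scales, with signals below the floor of 82.2 drawn at the floor. Coloured points are 4 fixed gene lists, the solid line marks equal signal and the dashed lines a 2-fold difference; 15 of 20 resident macrophage genes and 10 of 13 B cell markers lie on or below the lower dashed line, and 12 of 25 lysosome genes and 9 of 13 mesothelial and fibroblast markers on or above the upper one.

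Among genes above the floor on both arrays, the highest ratio of elicited over resident signal belonged to Sparc, a matrix glycoprotein (signal 90.2 on the resident and 4070 on the elicited array, 45.1-fold). It was followed by Ctsk, the collagen-degrading protease cathepsin K (419 and 17127, 40.9-fold), and Cd200, a ligand that restrains myeloid cells (36.2-fold). The collagen genes Col1a2 and Col3a1 were 32.9-fold and 27.7-fold higher. Pdpn, the membrane mucin podoplanin, was 27.0-fold higher and Mfge8, a bridge protein for uptake of apoptotic cells, had signals of 1039 and 25982. Pparg, a lipid-sensing nuclear receptor, was 23.7-fold higher from a resident signal of 85.5. The silent gene families alone had a 95th percentile of 92.7 on the resident array, so Sparc, Col3a1 (92.3) and Pparg were not above background there by that measure, and their folds and ranks are uncertain. Mamdc2 (22.9-fold), the lipid droplet gene Hilpda (129 and 2842), Aig1 (18.4-fold) and the interleukin-7 receptor gene Il7r (17.7-fold) completed these 12 genes. The 3 probe sets of Sparc disagreed in size, with log2 ratios from 0.59 to 5.50. Sparc and both collagen genes are on the list of mesothelial and fibroblast markers, whose median log2 ratio was 1.98.

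Genes at or below the floor on the resident array reached high signals on the elicited one. The bounds below hold against the floor of 82.2 set over both arrays; against the 92.7 of the resident array alone they are 1.13-fold smaller (152-fold for Bex1 and 92.0-fold for Npy). Bex1, a small adaptor protein best known from neurons, had a signal of 14116 and was at least 172-fold higher. Npy, neuropeptide Y, had a signal of 8526 and was at least 104-fold higher. Stra6l, a retinol transporter, was at least 37.0-fold higher and the serotonin receptor gene Htr2b at least 28.4-fold higher. Fstl1 (at least 24.1-fold) and Dcn (at least 23.7-fold) encode secreted matrix proteins. Lrrc27 was at least 22.7-fold and Scgb1a1, a secretoglobin of airway epithelium, at least 21.3-fold higher.

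In the other direction, Alox15, the 12/15-lipoxygenase of resident macrophages, had a signal of 25979 on the resident array and was at least 316-fold lower on the elicited array. Timd4, a phosphatidylserine receptor, was at least 118-fold lower and the eosinophil-attracting chemokine gene Ccl24 at least 72.1-fold lower. Coagulation factor gene F5 (at least 44.5-fold), St8sia6 (at least 39.6-fold) and Nt5e, the ectonucleotidase CD73 (at least 35.2-fold), were likewise at or below the floor on the elicited array. So were Ly6d (at least 29.0-fold) and H2-Ob (at least 27.6-fold), both known from B cells.

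Among genes measured on both arrays, the lowest ratios included the immunoglobulin genes Igkv8-30 (52.4-fold lower) and Ighm (50.5-fold lower) and the B cell surface gene Ms4a1 (5281 and 139). Igkv8-30 belongs to a large family of near-identical genes and was read by a probe set that can hybridise to several of them, so its identity is uncertain. The 4 probe sets of Ighm spanned log2 ratios from -5.66 to -0.29. Innate immune genes in this group were Fpr2, a formyl peptide receptor (46.2-fold lower), Cfb, complement factor B (44.2-fold), Adgre4 (43.4-fold), the scavenger receptor gene Marco (37.9-fold) and the B cell chemoattractant gene Cxcl13 (35.9-fold). Adgb (41.8-fold), Ltbp1 (41.7-fold), Tgfb2 (31.9-fold) and Serpinb2 (30.5-fold) completed it. Ltbp1 and Tgfb2 encode a latency-binding protein and a ligand of the TGF-beta family. The 3 probe sets of Ltbp1 ranged from -5.38 to -0.78.

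**Figure D2:**
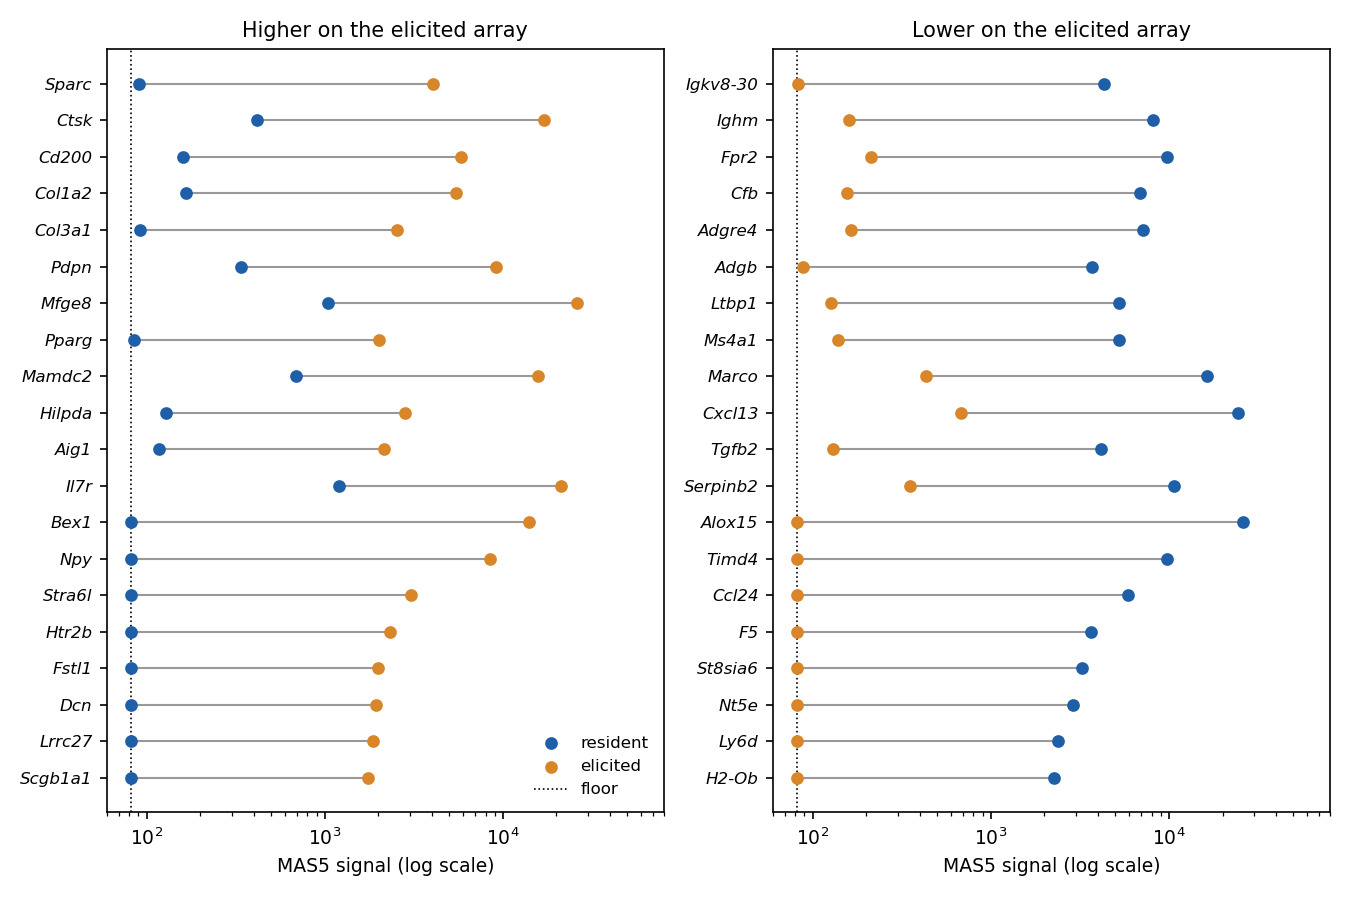
MAS5 signals (x axis, log scale) on the resident and elicited arrays of the 20 genes named for the highest ratios (left) and the 20 named for the lowest (right), 1 line per gene. The dotted line is the floor of 82.2, at which lower signals are drawn; the widest gaps are those of Alox15 (at least 316-fold) and Bex1 (at least 172-fold), both against that floor.

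The list of resident large peritoneal macrophage genes was lower on the elicited array almost throughout. Of 20 measured members, 15 were at least 2-fold lower, 1 was at least 2-fold higher and 4 lay within 2-fold. The median log2 ratio was -2.24, below all 10000 matched random lists (-2.87 with the floor at the 99th percentile). Besides Alox15, Timd4, F5 and Ltbp1, the joint lubricant gene Prg4 was 28.3-fold lower and the complement receptor gene Vsig4 was 4.92-fold lower. Gata6, the transcription factor that specifies these macrophages, was 4.44-fold lower (1822 and 411), with log2 ratios of its 3 probe sets from -2.35 to -0.33. Icam2, a surface marker of the same cells, was 1.86-fold lower, which is within the threshold. The member that was higher was Cd5l, a macrophage scavenger protein (5.58-fold).

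Of 12 measured pan-macrophage genes, 8 were within 2-fold, 1 was at least 2-fold higher and 3 were at least 2-fold lower. These counts depended on the scaling, with 3 higher and 3 lower with equal medians and 1 higher and 5 lower with loess. The signal of Csf1r, the receptor for the macrophage growth factor CSF1, was 36845 on the resident and 32074 on the elicited array, and its 3 probe sets ranged from -1.76 to -0.20 in log2 ratio. Lysozyme gene Lyz2 was 1.25-fold and Cd68 1.76-fold higher. Adgre4, named above, was the lowest. Adgre1, which encodes F4/80, was 1.76-fold lower, Mertk 1.83-fold, Cd14 2.73-fold and Itgam, the integrin CD11b, 2.99-fold lower. The Fc receptor gene Fcgr1 was 2.55-fold higher. The list median of -0.18 lay at percentile 0.56 of matched random lists. It became 0.13 when the arrays were scaled to equal medians, while its percentile stayed at 0.80 or below under every scaling tried.

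Monocyte and monocyte-derived macrophage genes had no common direction. Of 14 measured members, 3 were at least 2-fold higher, 4 at least 2-fold lower and 7 within 2-fold (median -0.37, percentile 1.25, but 9.05 with quantile normalization and 5.40 with loess). The calcium-binding protein genes S100a6 (5.84-fold) and S100a4 (3.47-fold) and Chil3 (3.14-fold) were higher. Plac8 was 23.4-fold, the fibronectin gene Fn1 2.41-fold and Ms4a4c 7.06-fold lower, and the haptoglobin gene Hp had a log2 ratio of -3.59. Ccr2, the chemokine receptor of inflammatory monocytes, had a log2 ratio of -0.43, and its 4 probe sets pointed both ways (-1.52 to 0.29). Ly6c2 was not analysed here. Over the 16 measured key macrophage genes, 6 were at least 2-fold lower and 1, Chil3, at least 2-fold higher (median -0.85, below all 10000 random lists).

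Genes of MHC class II antigen presentation were lower on the elicited array. Of 11 measured members, 8 were at least 2-fold lower and 3 within 2-fold, with a median log2 ratio of -1.34, below all 10000 random lists. The invariant chain gene Cd74 was 3.28-fold, H2-Eb1 2.53-fold and H2-Ab1 2.49-fold lower, while H2-Aa was 1.83-fold lower. The largest differences were in H2-Ob, H2-Oa (at least 9.74-fold) and H2-DMb2 (9.60-fold), whose products tune peptide loading. The class II transactivator gene Ciita was at least 4.07-fold lower, with log2 ratios of its 3 probe sets from -2.47 to -0.05.

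Markers of B cells moved in the same direction. Of 13 measured B cell markers, 10 were at least 2-fold lower on the elicited array (median -3.54, below all 10000 random lists, from -4.58 to -2.76 over the alternatives tried), among them Fcmr (28.1-fold) and Cd79b (23.9-fold). Cd22 (2269 and 4078) and Pax5 (141 and 159) went the other way, with log2 ratios of 0.85 and 0.18. All 13 were above the floor on the resident array and 7 on the elicited one, so the ratios of the rest could only be lower. Dendritic cell markers were lower too (5 of 7 at least 2-fold, median -1.54, percentile 0.005, from -2.98 to -0.80 over the alternatives), led by Btla (at least 17.9-fold), which B cells also carry, and Cd209a (at least 9.42-fold). Ccr7 (at least 4.26-fold), Dpp4 (at least 2.90-fold) and Kmo (at least 2.19-fold) were the others. All 7 dendritic cell markers were above the floor on the resident array and 1 on the elicited one, so the ratios of the rest could only be lower. Flt3, Itgae and Xcr1 were not above the floor on either array. Mast cell markers were at least 2-fold lower in 5 of 8 (median -1.31, percentile 0.01, from -4.67 to -0.61 over the alternatives), led by carboxypeptidase gene Cpa3 (at least 13.6-fold), Cma1 (at least 7.35-fold), Mcpt4 (at least 3.24-fold), Kit (at least 2.94-fold) and Tpsb2 (at least 2.09-fold). The same limit holds here, with all 8 above the floor on the resident array and 1 on the elicited one. Hdc and Ms4a2 were not above the floor on either array.

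The elicited array instead carried markers of mesothelium and fibroblasts, the lining and connective tissue cells of the cavity wall. Of 13 measured members, 9 were at least 2-fold higher and none lower (median 1.98, above all 10000 random lists). The median holds floored members at their bound, and was 4.02 with a pseudocount of 1 and 4.92 for the 4 genes above the floor on both arrays. Sparc and Col3a1, which are among these 4, were not above the 92.7 of the silent families on the resident array. Beyond Sparc, Col1a2, Col3a1 and Dcn, the growth factor receptor gene Pdgfra was at least 9.19-fold higher and the epithelial keratin gene Krt8 was 3.94-fold higher. All 13 were above the floor on the elicited array and 4 on the resident one, so the ratios of the rest could only be higher. Several mesothelial and epithelial members were dim on the elicited array. Krt19 (89.2), Krt7 (99.4), Wt1 (156) and Lrrn4 (162) were under the 99th percentile floor of 174 there, and Upk3b reached 244. Msln was not above the floor on either array.

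Other cell type markers were sparse. Neutrophil markers were at least 2-fold lower in 4 of 7 measured members (median -1.16, percentile 0.10), namely Padi4 (6.38-fold), Mmp9 (3.26-fold), Csf3r (2.38-fold) and Mmp8 (2.24-fold). S100a8 (3663 and 4675) and Lcn2 went the other way, with log2 ratios of 0.35 and 0.45. The neutrophil genes Cxcr2, Elane, Ltf, Mpo, Ngp and S100a9 were not above the floor on either array. Mmp9 and Mmp8 are also on the list of extracellular proteases. Of 6 measured T cell markers, Cd3d (at least 3.55-fold) and Cd3g (at least 2.34-fold) were lower, Cd28 was 2.87-fold higher and Cd5 at least 1.67-fold lower (median -0.50, percentile 8.28, from -1.30 to -0.14 over the alternatives). Of 3 eosinophil markers, Alox15 was lower and Siglecf 3.15-fold higher, and Il5ra was at least 1.51-fold lower (median -0.60, percentile 10.9). Among 5 platelet markers, Ppbp was at least 7.25-fold lower, Gp9 was at least 1.49-fold higher, and Pf4, Itga2b and Treml1 were within 2-fold (median -0.34, percentile 21.7, turning to 0.11 with quantile normalization and 0.01 with loess). Of the erythroid markers (2 measured, median -1.09) Epor (2.16-fold) and Alas2 (at least 2.09-fold) were lower, and of the NK cell markers Klrd1 (at least 1.88-fold lower) was the one above the floor.

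Classical inflammatory genes were lower on the elicited array, as were markers of B cells (median -3.54) and dendritic cells (median -1.54), which also carry Cd86, Cd40 and Cd80 of this list. Of 18 measured members, 13 were at least 2-fold lower and none was at least 2-fold higher (median -1.40, below all 10000 random lists). Acod1, which makes the antimicrobial metabolite itaconate, was 13.2-fold lower, the cytokine gene Il1b 9.48-fold, the costimulatory gene Cd86 6.65-fold and the adhesion gene Icam1 4.84-fold lower. The prostaglandin synthase gene Ptges had a log2 ratio of -2.58. The signal of Tnf was 449 on both arrays. Nos2, the inducible nitric oxide synthase gene, was not above the floor on either array.

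Chemokine genes split. Of 20 measured members, 8 were at least 2-fold lower and 4 at least 2-fold higher (median -0.31, percentile 3.79, but 0.25 with quantile normalization and 0.15 with loess, outside the central 95%). The neutrophil attractants Cxcl3 (at least 26.7-fold) and Cxcl2 (11.5-fold) were lower along with Ccl24 and Cxcl13. The monocyte attractants Ccl2 (4.57-fold), Ccl7 (at least 4.17-fold) and Ccl8 (86.7 and 259) were higher, as was Cxcl10 (at least 2.39-fold). The resident signal of Ccl8 was below the 92.7 of the silent families there.

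Interferon-stimulated genes also split, with 5 of 21 at least 2-fold higher (3 with the floor at 92.7) and 4 at least 2-fold lower (median 0.21, percentile 96.0). The antiviral gene Rsad2 was 6.95-fold, Cmpk2 at least 3.43-fold and Oas3 at least 3.20-fold higher. Ifit3 (at least 2.11-fold) and Ifit1 (at least 2.04-fold) pass the threshold only with the floor over both arrays, and their bounds are 1.87-fold and 1.80-fold with the other. The GTPase genes Gbp3 and Gbp2 were 5.23-fold and 3.53-fold lower, Oas2 was 3.64-fold and Stat2 2.32-fold lower. The median turned to -0.16 when arrays were scaled on the hybridisation controls. Without rescaling it was -0.03 for genes above the floor on both arrays and -0.26 for genes above 4 times the floor. Its percentile was 98.5 with quantile normalization and 99.25 with loess, above the central 95%. Of 18 Toll-like receptor and adaptor genes, 4 were at least 2-fold lower and none at least 2-fold higher (median -0.26, percentile 4.27, turning to 0.06 with equal medians). These were Tlr2 (11.5-fold), Irak3 (3.33-fold), Tlr7 (3.32-fold) and Cd14.

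Alternative activation genes had no common direction. Of 15 measured members, 3 were at least 2-fold higher and 4 at least 2-fold lower (median -0.07, percentile 32.6, 0.08 with equal medians). The mannose receptor gene Mrc1 was 3.96-fold and the lectin gene Clec10a 2.62-fold higher, with Chil3. Ccl24, Retnla (5.95-fold) and the transcription factor gene Irf4 (5.71-fold) were lower, with Ccl22 (at least 2.44-fold). Arg1, which encodes arginase, was 1.48-fold higher.

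Receptors for uptake differed in both directions. Of 22 measured scavenger and phagocytic receptors, 9 were at least 2-fold lower and 4 at least 2-fold higher (median -0.64, below all 10000 random lists). Clec4n, which encodes the fungal receptor dectin-2, was 28.3-fold lower, Olr1 18.2-fold and Axl 3.61-fold lower, besides Timd4 and Marco. Fcgr4 was 9.73-fold higher and Trem2, a lipid receptor, 4.82-fold higher. Complement genes were at least 2-fold lower in 4 of 12 members and at least 2-fold higher in 1 (median -0.40, percentile 0.22). Beside Cfb, Vsig4 and Itgam, properdin gene Cfp was 2.34-fold lower, and the integrin gene Itgax was 2.17-fold higher.

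Extracellular proteases and inhibitors had 4 of 16 members at least 2-fold higher and 5 at least 2-fold lower (median 0.09, mean -0.13, percentile 52.3). The median turned to -0.28 on the hybridisation controls. The inhibitor genes Timp3 and Timp1 were 5.19-fold and 4.53-fold higher, with Adam8 (4.61-fold) and the elastase gene Mmp12 (2.59-fold). Serpinb2, the antiprotease gene Slpi (7.46-fold), Mmp9, Mmp8 and Mmp2 (2.19-fold) were lower. Iron handling genes had a median of 0.14 and a mean of -0.50 (percentile 50.2), with 4 of 13 at least 2-fold lower and 1 higher. The median was negative with quantile normalization (-0.08), loess (-0.33) and the hybridisation controls (-0.26). Ceruloplasmin gene Cp was 14.1-fold lower (log2 ratios of its 7 probe sets from -3.99 to -0.11), the haemoglobin receptor gene Cd163 at least 3.34-fold and Ireb2 2.06-fold lower, with Hp (log2 ratio -3.59). The iron exporter gene Slc40a1 was 2.33-fold higher, but its other probe set had a log2 ratio of -0.89.

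As deposited, lysosome genes were higher on the elicited array in all 25 measured members, 12 of them at least 2-fold. The median log2 ratio was 0.93, above all 10000 random lists of equally bright genes. After Ctsk, the largest ratios were those of the proton pump subunit gene Atp6v0d2 (12.7-fold), Gpnmb (5.57-fold, signal 45166 on the elicited array) and the alpha-galactosidase gene Gla (4.20-fold). The acid lipase gene Lipa was 2.34-fold and the cathepsin gene Ctsl 2.51-fold higher. The median ranged from 0.56 to 1.24 over the scalings tried, but the number at least 2-fold higher was 16 with equal medians, 6 with quantile normalization and 5 with loess or on the hybridisation controls.

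Lipid genes did not share a direction. Of 15 cholesterol efflux and LXR genes, 3 were at least 2-fold higher and 4 at least 2-fold lower (median -0.01, percentile 19.995, with a median of 0.30 with equal medians and percentile 2.40 with loess). Abcg1, a cholesterol exporter, was 4.60-fold higher with Pparg. The LXR gene Nr1h3 was 2.04-fold higher. Apoc1 (10.8-fold), Abca1 (3.22-fold) and Mylip (2.49-fold) were lower, as was the desaturase gene Scd1 (1220 and 122), whose 2 probe sets had log2 ratios of -3.32 and -0.93. Cholesterol synthesis and uptake genes were within 2-fold in 16 of 18 members (median -0.01, percentile 52.6), the others being Mvd (2.66-fold lower) and the regulator gene Srebf2 (2.43-fold lower). Dhcr7 (1.55-fold higher) and Insig1 (1.51-fold lower) stayed within the threshold.

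Of 14 glycolysis genes, 8 were higher and 6 lower by any amount, 5 at least 2-fold higher and 1 at least 2-fold lower (median 0.50, percentile 94.5, within the central 95% of random lists; 0.81 with equal medians and 0.13 on the hybridisation controls). The higher ones were hexokinase gene Hk3 (6.97-fold), Tpi1 (3.06-fold), Pgam1 (3.03-fold), the lactate dehydrogenase gene Ldha (2.89-fold) and the glucose transporter gene Slc2a1 (2.27-fold), and Pfkl was 2.15-fold lower. Oxidative phosphorylation genes were higher in 25 of 26 members, but 25 were within 2-fold, and the median of 0.47 lay at percentile 74.3 of equally bright genes. That median was 0.13 after removing the loess trend and 0.10 on the hybridisation controls, but 0.78 with equal medians, where 7 members were at least 2-fold higher. Cox7a2 (2.05-fold) was the member past the threshold as deposited. Cycs (1.92-fold), Ndufb8 (1.86-fold, with probe sets pointing both ways) and Ndufa1 (1.82-fold) were below it. Fatty acid oxidation genes were within 2-fold in 15 of 17 members (median 0.15, percentile 68.7, -0.22 on the hybridisation controls and 0.48 with equal medians, where 4 of 16 were at least 2-fold higher). The electron transfer gene Etfb was 2.57-fold higher and the coactivator gene Ppargc1b 3.27-fold lower. Acadl was 1.78-fold and Hadhb 1.72-fold higher, the latter with probe sets pointing both ways.

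Antioxidant genes of the NRF2 programme were lower: 6 of 16 by at least 2-fold and none at least 2-fold higher (median -0.42, percentile 0.07). Glutathione transferase gene Gsta3 was 16.9-fold, the cystine transporter gene Slc7a11 4.07-fold, Nqo1 3.31-fold and Sod2 2.56-fold lower. Unfolded protein response genes had 3 of 14 members at least 2-fold higher and 1 at least 2-fold lower (median 0.74, percentile 99.8, but 96.4 with quantile normalization and 96.05 with loess, inside the central 95%). The number at least 2-fold higher was 7 with equal medians (median 1.05) and 1 on the hybridisation controls. Asns, asparagine synthetase, was 5.26-fold higher, Trib3 at least 2.26-fold and Edem1 2.03-fold higher, and Herpud1 was 3.53-fold lower.

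Cell cycle genes were higher on the elicited array, as were mesothelial and fibroblast markers (median 1.98). Of 29 measured members, 13 were at least 2-fold higher and 1 at least 2-fold lower (median 0.83, above all 10000 random lists). Signals of most mitotic genes were low: Rrm2 reached 551 (at least 6.70-fold higher), Tpx2 395 (at least 4.81-fold), Birc5 373 (at least 4.54-fold) and Ube2c 416 (3.65-fold) on the elicited array. The 4 probe sets of Tpx2 pointed both ways. Pcna, the replication clamp gene, was 2.82-fold higher at a signal of 23888. Mki67, the Ki-67 antigen gene, went against the list at 3.23-fold lower, on 1 probe set. Immediate early and heat shock genes were divided, with 4 of 16 at least 2-fold higher and 4 at least 2-fold lower (median -0.12, percentile 23.2, 0.18 with equal medians). Atf3 (4.67-fold), Fos (4.13-fold), Dusp1 (3.23-fold) and Jun (3.11-fold) were higher, and Egr3 (at least 9.89-fold), Ier3 (4.61-fold), Nr4a1 (3.92-fold) and Junb (2.02-fold) lower.

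**Figure D3:**
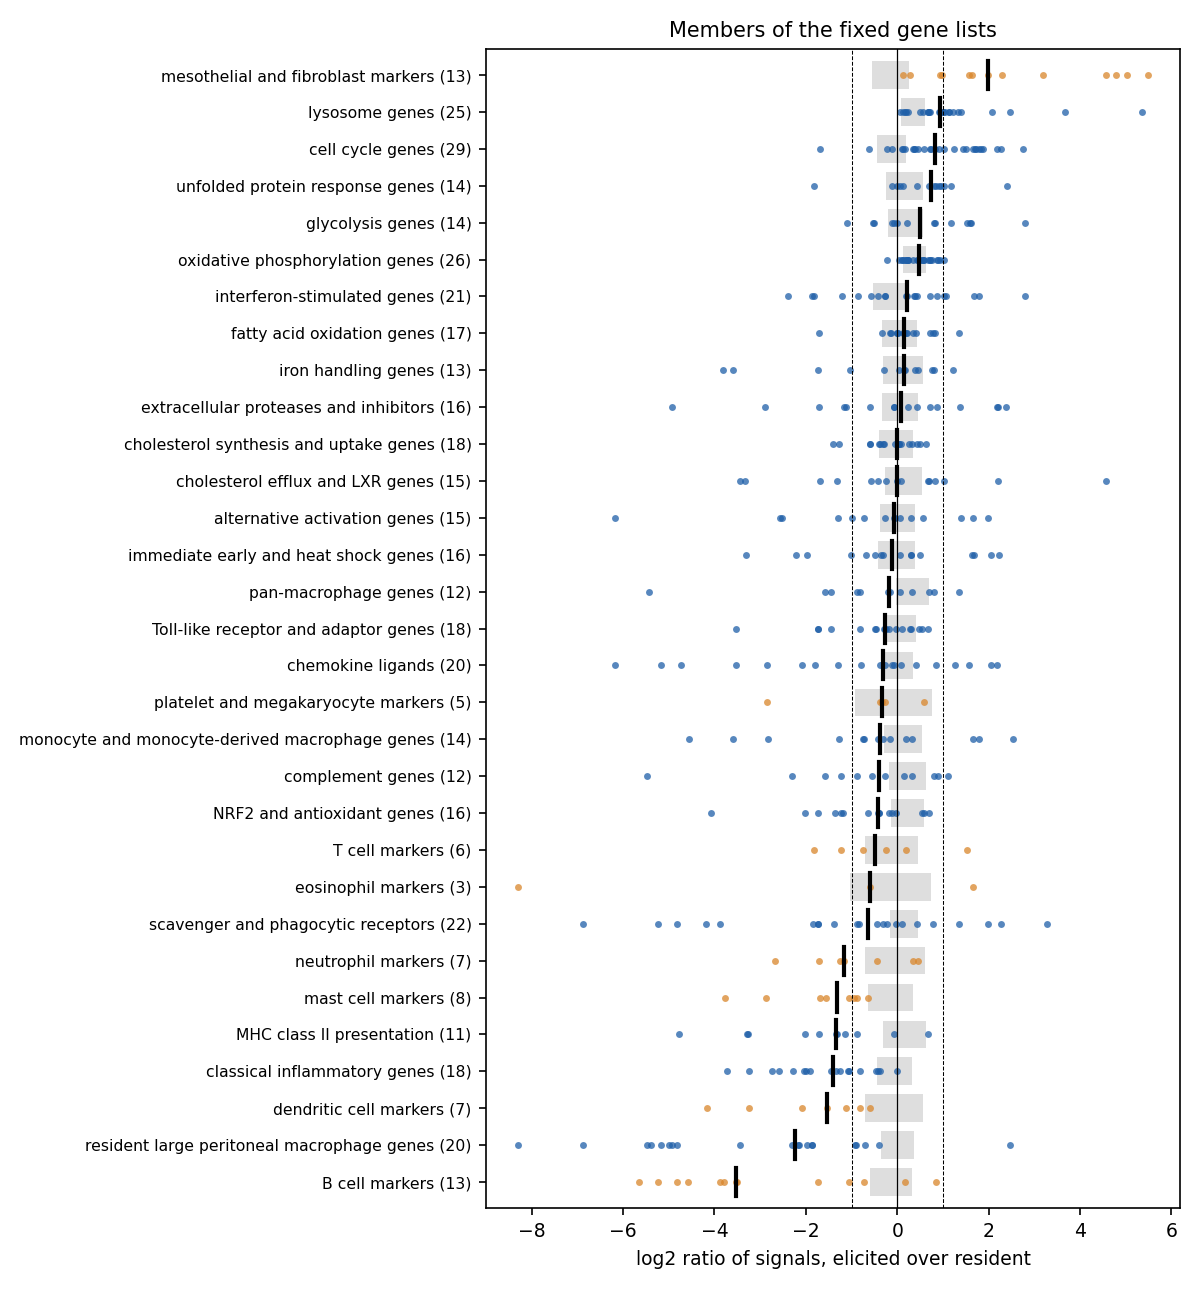
Log2 ratios of elicited over resident signal (x axis) for the measured members of each fixed list (1 line per list, number of members in parentheses), pathways in blue and cell type markers in orange. Black bars are list medians and grey bars the central 95% of medians of 10000 random lists matched on signal. Of the 31 list medians, 12 lie below the grey bar and 4 above it. The 1.55 of either kind expected by chance holds only for independent lists of independently varying genes. Some lists share members and genes of a list can vary together, so these counts are a description and not a test.

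Control genes bounded these readings. Of 10 housekeeping genes, 9 were within 2-fold (median 0.19, percentile 22.2). This median was 0.49 with equal medians but negative with quantile normalization (-0.05), loess (-0.10) and the hybridisation controls (-0.18). Rplp0 had a log2 ratio of 0.02 and Actb of 0.17, with -0.60 at its other probe set. The largest ratios were those of Gusb (2.25-fold higher), Tfrc (1.70-fold), Hprt (1.47-fold) and Polr2a (1.29-fold). The Y-linked genes Eif2s3y, Uty and Kdm5d were above the floor on both arrays and within 2-fold, and Xist was 111 on the resident array and at or below the floor on the elicited one. Their median log2 ratio was -0.49 (percentile 14.6).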

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

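The comparison of MHC class II genes with B cell markers was chosen, and its rule later extended to a second B cell list, after its result was seen; the other tests of this part were set out before their own values were known.

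Data outside the gene-level comparison also differed. Among probe sets without a gene name, 5 were at or below the floor on the resident array and above 4 times the floor on the elicited array, while 118 showed the opposite. The array's control for the murine B1 repeat, a short interspersed element, was 3.53-fold higher on the elicited array (4027 and 14216), whereas the B2 repeat control was 1.13-fold higher.

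The unnamed probe sets leaned to the resident array as a class. Of 3110 above the floor, 1060 (34.1%) were at least 2-fold lower and 59 at least 2-fold higher on the elicited array. A trend with signal shared by named probe sets is argued against as the whole cause, since 1000 draws of named probe sets matched on signal gave 15.4% on average and at most 17.6%. Other probe sets of named genes, meaning those dimmer than the representing one, were at least 2-fold lower in 19.2% of 9619 cases. This was above the 14.1% that was the highest of 1000 matched draws from representing probe sets, but below the 34.1% of unnamed probe sets. Transcript parts outside the main 3' end remain a candidate, which this result cannot decide because positions of probe sets were not used. What the unnamed probe sets read is not known here, and the thioglycollate treatment stays open and untested.

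B cell and MHC class II genes were lower on the elicited array together. B cells carried over in the resident culture are a candidate source: a second list of B cell genes had a median log2 ratio of -1.54, below all 10000 matched random lists, with 9 of 16 members at least 2-fold lower, although adherence and washing should remove B cells. Ighm reached 8119 and Ms4a1 5281 on the resident array. All 16 genes of the second list were above the floor there and 10 on the elicited array, where Blnk was 2.24-fold higher at 13826. The ratios of the rest could only be lower. Whether B cells were the only source of class II RNA was not decided by these ratios, because the B cell lists differ. H2-Aa, H2-Ab1, H2-Eb1 and Cd74 had a median of -1.33. This was far from the -3.54 of the fixed B cell markers but within 1 probe-set SD of the second list. On the elicited array these class II genes had signals from 3167 to 9404. Of the 13 fixed B cell markers, Cd22 had 4078 there and all others 161 or less. The second list held some brighter genes there, such as Blnk, Tnfrsf13b (1422) and Cd180 (1335). How much of the class II difference comes from B cells and how much from macrophages stays open, as does the thioglycollate treatment itself.

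Collagen and matrix genes were higher on the elicited array. Fibroblasts carried over in that culture are a candidate source, with a second list at a median of 1.55, above all 10000 random lists and with 12 of 17 members at least 2-fold higher; Bgn reached 1028 and Col5a2 869. The fibroblast genes Lum, Mfap2 and Pdgfrb were not above the floor on either array, so the match is incomplete. Mesothelial cells are a second candidate, with a median of 1.12 over 8 members, also above all random lists. Their elicited signals were low, from 94.4 to 434, and Msln and Cldn15 were not above the floor on either array. On the resident array 7 of the 17 fibroblast members and 1 of the 8 mesothelial members were above the floor. The ratios of the rest could only be higher, so the place of both lists among random lists was partly fixed beforehand and is weak support. These tests do not separate carried-over cells, which adherence need not remove, from matrix gene expression by the elicited macrophages after thioglycollate, which stays open.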

How the results depend on the processing

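No paired analysis was possible because each group has 1 array, and for the same reason no replicate could be left out and no other split of the samples exists. Of 161 named genes followed through 12 alternatives, none that was at least 2-fold apart changed sign where it was still measured. Some alternatives left named genes out: 119 remained with genes above the floor on both arrays and 144 with genes above 4 times the floor. Log2 ratios of the named genes moved by less than the probe-set SD of 0.48 in 1706 cases and by more in 158. Medians of 33 lists changed sign in 28 cases over 12 lists, of which 1 case, that of the pan-macrophage genes, concerned a median outside the central 95% of random lists as deposited. Apart from that case, medians moved by more than the probe-set SD in 17 and by less in 369, the other sign changes included. Scaling to equal medians gave 1640 genes at least 2-fold higher and 848 lower, with all 848 among the main 1357, and turned the pan-macrophage median from -0.18 to 0.13. Scaling on the hybridisation controls, chosen after seeing the data, gave 525 and 2367. A floor of 92.7 from the resident array alone, also chosen then, gave 889 and 1301. A 4-fold threshold left 203 and 316 by its construction. With the floor at the 99th percentile the medians were -2.87 for resident macrophage genes, -2.76 for B cell, -0.61 for mast cell and -0.80 for dendritic cell markers, and the probe-set SD was 0.41. With a pseudocount of 1 and no floor they were -4.57 (B cell), -1.30 (T cell), -1.11 (eosinophil), -4.67 (mast cell), -2.98 (dendritic cell) and 4.02 (mesothelial and fibroblast). The mean over probe sets gave -2.85 for B cell markers. Genes above the floor on both arrays gave -4.58 for B cell and 4.92 for mesothelial and fibroblast markers. Genes above 4 times the floor gave -2.87 for resident macrophage genes, -0.80 for chemokines, -2.66 for dendritic cell and 4.56 for mesothelial and fibroblast markers. Apart from the filters and the floor, which act through the genes they leave in or the bound they set, the cause was not tested. Low signals limit these values: 931 genes were above the floor on the resident array alone and 748 on the elicited array alone, so their ratios are bounds. Both counts depend on the floor shared by the arrays.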

Other observations

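The lists of this part were written after the main results were seen, and no test was chosen after its own value was known.

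Subunits of the vacuolar proton pump other than those on the lysosome list were higher on the elicited array in 11 of 11 cases, 9 of them at least 2-fold. The largest ratios were those of Atp6v1c1 (3.41-fold, 9490 and 32343) and Atp6v0a1 (3.17-fold). The group's median log2 ratio of 1.16 lay at percentile 99.99 of equally bright random lists and ranged from 0.78 to 1.46 over the scalings tried, although 2 of the 11 were at least 2-fold higher with quantile normalization, loess or the hybridisation controls and all 11 with equal medians. The 4 probe sets of Atp6v0a1 had log2 ratios from 0.12 to 2.05. A coordinated difference in pump subunits is thus consistent with these arrays, as a hypothesis from 1 array per group. An osteoclast and cell fusion programme, prompted by Ctsk and Atp6v0d2, was not borne out as a group and stays undecided. Its median of 0.21 lay at percentile 70.2 (-0.07 on the hybridisation controls), with Acp5 5.20-fold, Tcirg1 2.64-fold and Itgb3 2.09-fold higher but Nfatc1 2.60-fold and Dcstamp 2.22-fold lower.

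The higher Pparg signal, whose size is uncertain because the resident signal was near background, prompted a test of its target genes, without Fabp4 and Cd36. Their median log2 ratio was 0.74, at percentile 97.97 of random lists (at the edge of the central 95% with loess). Of 14 genes on the list, 9 had a probe set naming them alone and 5 were above the floor. Fabp4 and Cd36 had log2 ratios of 0.70 and 0.79, under 2-fold. The percentile is narrowly past the central 95%, which is weak support for higher target expression. It rests on 5 measured genes, of which Slc27a1 (5.27-fold) and Plin2 (2.90-fold) were at least 2-fold higher and Lipe was 2.87-fold lower. A hypoxia response, prompted by Hilpda and Ndrg1, was not decided. The other hypoxia genes had a median of 0.12 and a mean of -0.09, at percentile 84.6, with 15 of 17 within 2-fold. Car9 was 3.07-fold higher and Ddit4 at least 4.23-fold lower. The median of these genes was 0.42 with equal medians, 0.37 with quantile normalization, 0.30 with loess and -0.25 on the hybridisation controls. Cytosolic ribosomal protein genes were within 2-fold in all 18 cases, with a median of 0.16 at percentile 3.46 of equally bright genes. That median was 0.47 with equal medians (percentile 3.7), -0.16 with quantile normalization, -0.30 with loess (percentile 0.95) and -0.21 on the hybridisation controls.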
